A study of Homo sapiens with 36 samples.

How the data were processed

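The libraries came from HUES6, an established human embryonic stem cell line, either unmodified (WT) or carrying a knockout of RBPMS (KO), an RNA-binding protein. Cells were grown in FTDA medium, a defined medium for pluripotent stem cells, per the labels. Ribosomes were held on their mRNAs with cycloheximide at 100 ng/ml for 5 min, and lysates were separated by polysome profiling, in which a gradient sorts RNA by the number of ribosomes bound to it. Each culture gave 6 kinds of sample: the unfractionated Input, the 40S and 80S fractions, the disome fraction and 2 polysome fractions named Polysome1 and Polysome2. RNA was extracted with Trizol, and libraries were made from equal amounts of RNA with a stranded poly(A) mRNA kit and sequenced as paired 75 nt reads, per the labels' protocols. With equal RNA input, the values describe the composition of each fraction and not the amount of RNA in it.

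There were 36 libraries in 12 groups of 3, from 2 genotypes and 6 fractions. Groups and replicate numbers were taken from the sample descriptions, in which a genotype and a number name each of the 6 cultures. The description of KO replicate 3 calls its Input sample Input2, while the other 5 cultures have Input. Whether it is a repeat preparation is not given in the sources used here. Nothing in the labels says whether cultures of one genotype came from separate clones or days, so the p-values do not reach beyond these cultures. The main fit takes the 36 libraries as independent, although they come from 6 cultures. Its p-values rest on a spread pooled over all 12 groups, and not on the spread between the cultures of each genotype alone.

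The deposited table held TPM (an abundance unit scaled to a fixed library total) for 223367 versioned Ensembl transcript IDs and 92 IDs of the External RNA Controls Consortium (ERCC) spike-in set. The submitters' processing notes name kallisto and sleuth, with versions not given in the sources used here, and the genome build hg19. In TPM an estimated read number is divided by transcript length and scaled so that each library sums to 1000000. The values keep no record of sequencing depth, so the depth behind each value is unknown and no counting interval is given. A value of 0 is a listed estimate and not a count. No column of the table was left unused.

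The table gives no gene names. The gene table given for naming held 59792 genes, and 0 of them had an Ensembl ID, so no transcript was matched to a gene. RBPMS itself and 26 gene lists fixed before the data were examined were not analysed here. Transcripts are reported by ID, with a limit of 2 that rose and 2 that fell. Among the tested transcripts, 3532 had values identical to those of another transcript in all 36 libraries. Estimates for transcripts that share sequence can be split between IDs, so a change of one ID can reflect a shift between isoforms.

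The plan fixed before the data were examined assumed read counts and named a limma test for the case that the table held TPM only. That test was used. It was run on single transcripts, because the planned sum over the transcripts of a gene needs gene names. The planned filter on counts was replaced by a filter on TPM. ERCC rows were set aside. Transcripts with at least 1 TPM in at least 3 libraries were kept, which left 51052. Values were transformed as log2(TPM + 1), and a linear model with 12 group means was fitted to all 36 libraries with limma 3.58.1 in R 4.3.3, with 24 residual degrees of freedom and a variance trend on abundance. The fit takes libraries of one culture as independent, so for KO against WT these 24 degrees of freedom overstate the replication given by the cultures. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. A log2 fold change on this scale understates the change of low transcripts. The 14 comparisons were: KO against WT in each of the 6 fractions, the KO against WT difference of each of 5 fractions relative to Input (an interaction term, called a shift), and WT 40S, 80S and Polysome2 against WT Input.

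Named transcripts were the 2 with the largest rise and the 2 with the largest fall in KO Input among those past the threshold, with a mean of at least 5 TPM in the higher group and no overlap between the replicates of the 2 groups. The fixed rule asked for more names and for a minimum in CPM. TPM replaced CPM, and the number was reduced because no gene names were given.

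The number of transcripts at 1 TPM or more, the share of all TPM in the 10 most abundant transcripts, and the ERCC total were computed for each library. KO and WT were compared by two-sided exact permutation tests of the difference in means (of log2 values for ERCC), with 18 tests adjusted together. With 3 against 3 the smallest p these tests can give is 0.1. The tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

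The model was tested on simulated data for the KO against WT comparison in Input, over 51052 transcripts with 40 transcripts changed at each of 5 sizes. Of those, 0% were recovered at a log2 change of 1, 2.5% at 2, 35.0% at 3, 52.5% at 4 and 75.0% at 5. None of the 66 calls made was false in that comparison, and 1 call was made in the simulated 80S comparison, which held no change. The changed transcripts were drawn from those with a mean log2(TPM + 1) above 3. The simulated noise was independent between libraries, with the same SD for a transcript in all groups. It held neither the resemblance of libraries of the same culture nor the larger spread among KO replicates, so false calls from these could not appear.

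Alternatives were a pseudocount of 0.1, no filter, fitting only the libraries compared, a replicate block, and leaving out each culture in turn. Added after the data were seen were a stricter filter, a random block for culture, 3 other scalings, and leaving out 2 KO cultures together. The planned count-based tests and their normalizations, and scaling without mitochondrial and ribosomal protein genes, were not run, because the table held TPM without gene names.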

Results

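RNA from 6 fractions of a polysome gradient experiment was sequenced in HUES6 human embryonic stem cells that were unmodified (WT) or lacked RBPMS (KO). The unfractionated Input, 40S, 80S, disome, Polysome1 and Polysome2 samples were each measured in 3 WT and 3 KO cultures, giving 36 libraries. RBPMS is an RNA-binding protein, and the design asks which transcripts change in the cell as a whole and which change in their distribution over ribosome-bound fractions when it is lost. The values were TPM per transcript, each library summed to 1000000, and sequencing depth is unknown. The table pairs no transcript with a gene, so the level of RBPMS was not analysed here and the knockout was taken from the labels.

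The fractions differed in how many transcripts they held. In WT, 36216 ± 1896 transcripts (SD, n = 3) reached 1 TPM in Input, 13206 ± 3732 in 40S, 26289 ± 1409 in 80S, 30592 ± 5841 in disome, 31091 ± 1276 in Polysome1 and 28985 ± 1391 in Polysome2. The 10 most abundant transcripts took 29.6% ± 4.41 of WT 40S (SD, n = 3), 16.0% ± 3.07 of WT Input and 8.37% ± 2.74 of WT Polysome2. The 40S libraries were made up of fewer transcripts than any other WT fraction, with no overlap between the replicates of 40S and those of the other 5 fractions.

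KO libraries held fewer transcripts in Input, where all 3 KO values lay below all 3 WT values. The KO Input mean was 23987 ± 6606 transcripts at 1 TPM (SD, n = 3), and the exact permutation p was 0.1 (two-sided, adjusted 0.225), the smallest that 3 against 3 can give. KO Input replicates 1 and 2 held 18666 and 21914 transcripts and replicate 3 held 31380. The same 2 KO cultures were lowest in the 80S, disome, Polysome1 and Polysome2 fractions, with 18407 and 18851 transcripts in 80S against 27832 in KO replicate 3. In those fractions and in 40S the KO and WT replicates overlapped, with exact permutation p between 0.2 and 0.8. In 40S the 10 most abundant transcripts took 44.3% ± 13.6 of KO libraries (SD, n = 3) and 29.6% ± 4.41 of WT libraries, without overlap (exact permutation p = 0.1, adjusted 0.225). For the 100 most abundant transcripts this order turned, at 0.977 times the WT mean. In Input the 100 most abundant took 55.2% ± 11.3 of KO libraries (SD, n = 3) and 39.8% ± 1.06 of WT libraries, without overlap. For the 10 most abundant the KO and WT Input libraries overlapped, at 29.0% ± 12.5 and 16.0% ± 3.07 (SD, n = 3). One library, KO disome replicate 1, had 70.5% of its TPM in 10 transcripts, against 13.9% and 8.35% in the other KO disome libraries.

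**Figure D1:**
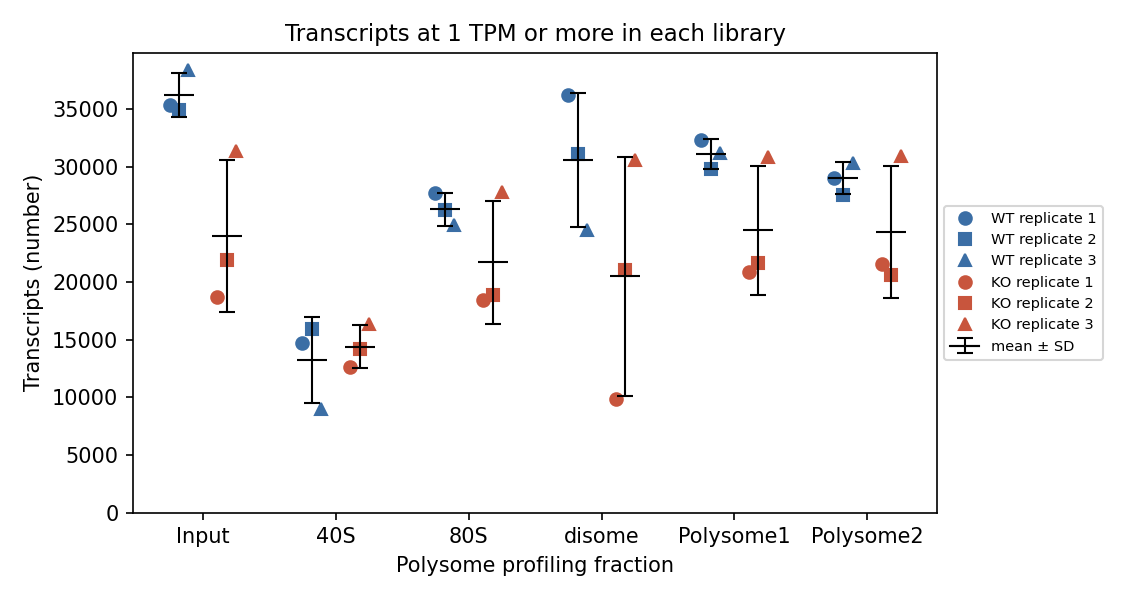
Number of transcripts at 1 TPM or more (vertical axis) in each of the 36 libraries, by fraction (horizontal axis), with WT in blue and KO in red, a symbol per replicate, and the mean ± SD of 3 replicates in black. The KO Input libraries (18666, 21914 and 31380 transcripts) all lie below the WT Input libraries.

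Replicates agreed less among KO cultures than among WT cultures in every fraction but 40S. At least 2 of the 3 KO pairs lay below all 3 WT pairs there, and in Input all 3 did. Across the 51052 tested transcripts, which are not independent replicates, Pearson's r of log2(TPM + 1) between WT replicates was 0.905 to 0.933 in Input and 0.899 to 0.944 in Polysome2, and 0.553 to 0.880 and 0.613 to 0.904 between KO replicates. In 40S it was 0.631, 0.641 and 0.932 between WT replicates and 0.613, 0.738 and 0.872 between KO replicates. In each of the 6 fractions the highest KO value was that of replicates 1 and 2. KO Input replicate 3 correlated with the WT Input mean at 0.911, while KO Input replicates 1 and 2 did so at 0.462 and 0.590, below their correlations with the WT disome mean (0.717 and 0.834). No pair of libraries was identical, and the highest r between any 2 was 0.957.

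The transcripts that mark the unfractionated sample were read in the KO libraries. In WT, 72 transcripts reached 5 TPM in all Input libraries and stayed below 1 TPM in every gradient fraction library, and 13 showed the reverse. Of the 72, 0% reached 1 TPM in KO Input replicates 1 and 2, and 58.3% did in KO Input replicate 3. Of the 13, 100% reached 1 TPM in KO Input replicates 1 and 2, and 46.2% did in KO Input replicate 3. In the KO gradient fractions at most 5.56% of the 72 were present, and 100% of the 13. A further 2193 transcripts of matched abundance in WT Input, found in all WT fractions as well, were present at 94.7% and 99.1% in KO Input replicates 1 and 2.

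**Figure D2:**
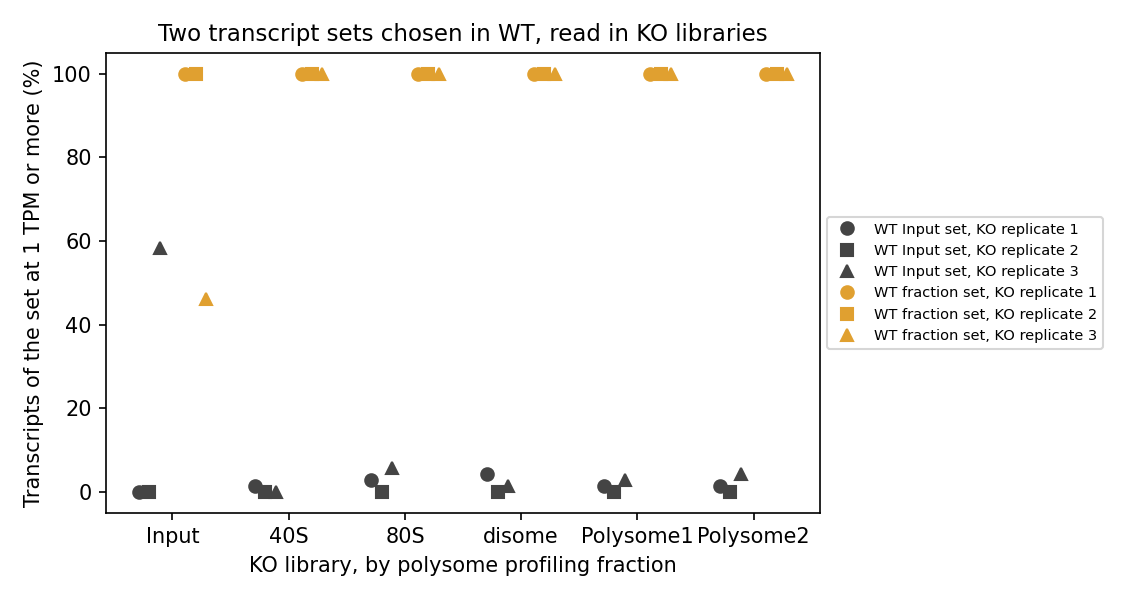
Percent of each transcript set at 1 TPM or more (vertical axis) in each KO library, by fraction (horizontal axis), with a symbol per replicate. Grey shows the 72 transcripts found in WT Input and absent from WT fractions, present in 58.3% of cases in KO Input replicate 3 and 0% in replicates 1 and 2; yellow shows the 13 transcripts with the reverse pattern.

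Loss of RBPMS was first compared with WT in the unfractionated Input. In KO Input 1008 transcripts were higher and 9184 were lower (limma, Benjamini-Hochberg adjusted p under 0.05, 51052 tested). The median log2 fold change was 2.40 among those that rose and -1.59 among those that fell, against -0.51 over all tested transcripts. ENST00000600794.1 rose by 8.99 on the log2 scale (SE 0.74, limma adjusted p = 3.273e-10). It was listed at 0, 0 and 1.09 TPM in WT Input and at 1319, 1148 and 182 TPM in KO Input. In the WT gradient fractions its means were 261 to 836 TPM, so the rise does not mean that WT cells lacked it. The size of this rise rests on values near 0 in WT Input. It was 11.48 with a pseudocount of 0.1, 5.76 after ERCC scaling and 7.16 with KO replicates 1 and 2 left out together. ENST00000464611.1 rose by 7.47 (SE 1.13, limma adjusted p = 1.7e-05), from 1.46, 454 and 2.18 TPM in WT to 3789, 5374 and 967 TPM in KO. The size of this change depends on WT replicate 2: it was 9.92 without that replicate (SE 0.80), and 6.15 and 6.34 without WT replicates 1 and 3 (SE 1.28 and 1.29). With only the Input libraries fitted the log2 change stayed at 7.47 with a larger error (SE 2.09, limma adjusted p = 0.1188). With KO replicates 1 and 2 left out together, which leaves 1 KO library, it was 5.99 (SE 1.89, limma adjusted p = 0.2), so the call ended in both settings with most of the change still present. ENST00000542931.6 fell, from 97.1, 81.6 and 100.2 TPM in WT Input to a listed 0 in all 3 KO Input libraries (limma adjusted p = 4.107e-06). Without KO replicates 1 and 2 the listed 0 remained, and the call ended (limma adjusted p = 0.09562) because the error grew from an SE of 0.90 to 1.74 with fewer libraries. ENST00000417652.5 fell from 88.7, 43.4 and 179 TPM to a listed 0, 0 and 5.96e-05 TPM (SE 0.32, limma adjusted p = 6.883e-15). That small p rests on a spread pooled over all groups, most of which list this transcript at 0. With only the Input libraries fitted, its SE was 0.56 (limma adjusted p = 0.04753). In that fit ENST00000600794.1 had an SE of 0.85 and ENST00000542931.6 one of 0.31 (limma adjusted p = 0.04851 and 0.02359).

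Lower calls were the majority in Input at every abundance, with a smaller share among abundant transcripts. Transcripts were divided into 5 bins of equal size by their mean TPM over the 6 Input libraries. In the lowest bin 336 calls were lower and 22 higher, a share of 93.9% lower. In the highest bin, above 6.87 TPM, 1364 were lower and 464 higher, a share of 74.6% lower. Bins by the mean over all 36 libraries, tried first, gave 45.2% lower in the highest bin, but that mean ranks transcripts found mainly in WT Input low, which ties the bins to the direction. The share of lower calls over all tested transcripts was 90.1%. With a filter of 10 TPM it was 63.0%, from 603 higher and 1028 lower. It was 68.9% after quantile normalization, 81.8% after median-of-ratios scaling and 99.8% after scaling to the ERCC total. These scalings moved the median log2 fold change of all transcripts from -0.51 to 0.00, -0.20 and -1.37. With only the 6 Input libraries in the fit, 40 transcripts were called, and with KO replicates 1 and 2 left out together 656 were. Leaving out single cultures gave 3861 calls without KO replicate 1, 3302 without KO replicate 2, 22990 without KO replicate 3, 6575 without WT replicate 2 and 6305 without WT replicate 3.

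In the main fit the same comparison in the polysome fractions gave fewer calls, divided more evenly between the directions. In Polysome2, 970 transcripts were higher and 1847 lower in KO, with a median log2 fold change of 2.27 among those that rose and -1.78 among those that fell, against -0.22 over all transcripts. In Polysome1, 809 were higher and 1960 lower, with medians of 2.07 and -1.75 against -0.32 over all. ENST00000600794.1 rose in both, by 2.87 in Polysome2 (SE 0.74, limma adjusted p = 0.02361) and by 3.20 in Polysome1 (SE 0.74, limma adjusted p = 0.01765). ENST00000464611.1 did not pass the test in Polysome2, with a log2 difference of 0.94 (SE 1.13, limma adjusted p = 0.6337). ENST00000417652.5 was listed at 0 in all 6 Polysome2 libraries. ENST00000542931.6 was listed at 0 in all 3 KO Polysome2 libraries and at 0, 0 and 41.2 TPM in WT, which did not pass the test (limma adjusted p = 0.2014).

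Calls in Polysome2 overlapped those in Input, from different libraries of the same cultures. Both lists use the same variance estimate per transcript, and libraries of one culture resemble each other, so the number shared by independent lists is not what a lack of genotype effect would give. Of the 1847 transcripts lower in KO Polysome2, 1099 were also lower in KO Input, where independent lists would share 332. Of the 970 higher, 198 were also higher in KO Input, where independent lists would share 19.2. For Polysome1 the shared numbers were 844 lower, against 353 for independent lists, and 155 higher, against 16.0. The lower lists of the lighter fractions shared numbers nearer to those of independent lists: 302 against 252 in disome, 65 against 49.3 in 80S and 1 against 0.899 in 40S. Their higher lists shared 3 against 0.415, 9 against 0.632 and 0 against 0.138.

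The polysome counts rested on the shared estimate of the spread and on which KO cultures were included. With only the 6 libraries of a fraction in the fit, limma called 0 transcripts in Polysome1 and 0 in Polysome2, with 11750 and 9258 at an unadjusted p under 0.05. Without KO replicate 3 the counts were 18612 in Polysome1 and 17515 in Polysome2, without KO replicate 1 they were 166 and 414, and without KO replicate 2 they were 27 and 273. Without WT replicates 1, 2 and 3 they were 884, 509 and 663 in Polysome1 and 595, 1196 and 1072 in Polysome2. With KO replicates 1 and 2 left out together, KO is a single library per fraction, and the spread comes from the other groups. In that fit 79 transcripts were higher and 17 lower in Polysome1, and 152 higher and 43 lower in Polysome2, which describes KO replicate 3 alone. The majority turned with a filter of 10 TPM, to 280 higher and 238 lower in Polysome1 and 493 higher and 344 lower in Polysome2. The share of lower calls in Polysome1 was 70.8%, and 61.2%, 78.9% and 99.4% after quantile, median-of-ratios and ERCC scaling. In Polysome2 it was 65.6%, and 65.9%, 77.1% and 99.6% in the same order, with median log2 fold changes of 0.01, -0.14 and -3.40. After ERCC scaling the polysome fractions had more calls than Input, at 39131 in Polysome1 and 39009 in Polysome2 against 6909. This scaling moves all transcripts of a library by 1 factor, so these counts follow the difference in ERCC totals. Of the 92 ERCC rows, 16, 9 and 15 were above 0 in WT Polysome1 and 15, 13 and 7 in WT Polysome2. In KO the numbers were 32, 32 and 20, and 37, 34 and 18.

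In the lighter fractions the number of calls in 40S depended on the processing, and most calls were lower in KO in 80S and disome. In 40S, 7 transcripts were higher and 5 lower, and the total was 138 with a pseudocount of 0.1, 1142 after quantile normalization and 2370 after median-of-ratios scaling. In 80S, 32 were higher and 274 lower, with medians of 2.48 and -1.82, and in disome 21 were higher and 1399 lower, with medians of 1.35 and -1.83. None of the 4 named transcripts passed the test in these fractions. ENST00000600794.1 differed by 1.07 in 40S, 1.65 in 80S and 0.93 in disome on the log2 scale (SE 0.74 each, limma adjusted p of 1, 0.2589 and 0.4789). Its levels were 826 ± 285 TPM in WT 80S and 2596 ± 880 TPM in KO 80S (SD, n = 3).

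With only the libraries of each fraction in the fit, limma called 0 transcripts in 40S, 80S and disome, with 3322, 7169 and 4102 at an unadjusted p under 0.05. Without KO replicate 3 the counts were 1241 in 40S, 11700 in 80S and 15382 in disome, without KO replicate 1 they were 98, 53 and 76, and without KO replicate 2 they were 2, 12 and 28. Without WT replicates 1, 2 and 3 they were 4, 5 and 32 in 40S, 70, 69 and 352 in 80S, and 93, 91 and 2975 in disome. With KO replicates 1 and 2 left out together, 80S had 27 higher and 7 lower and disome 74 higher and 15 lower, again from KO replicate 3 alone, with no spread of its own. In 40S the share of lower calls was 41.7%, and 59.1% and 74.5% after quantile and median-of-ratios scaling. In 80S it was 89.5%, and 71.1% after quantile normalization and 99.6% after ERCC scaling. In disome it was 98.5%, and 69.1% and 85.0% after quantile and median-of-ratios scaling.

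**Figure D3:**
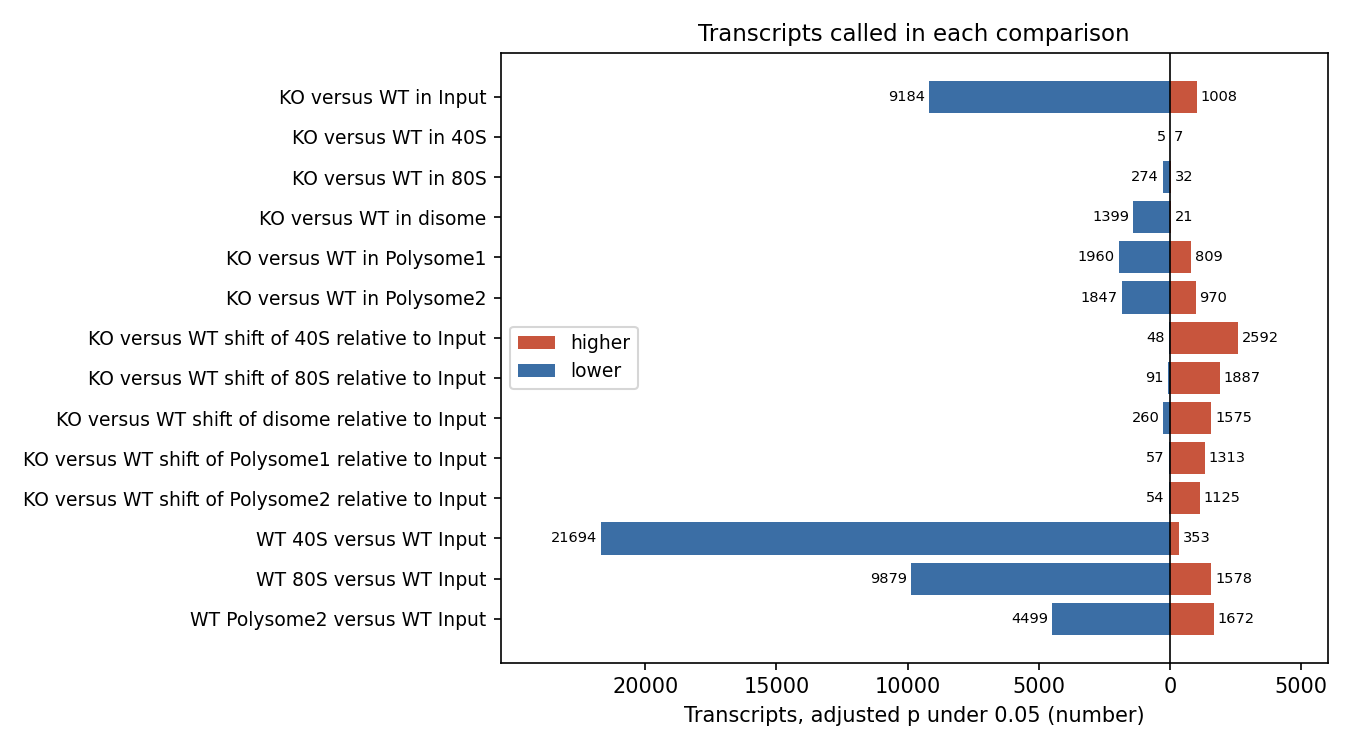
Number of transcripts past an adjusted p of 0.05 (horizontal axis) in each of the 14 comparisons (vertical axis), with higher transcripts in red to the right and lower ones in blue to the left. KO Input has 9184 lower and 1008 higher, and the 5 shifts are mostly positive.

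Whether a transcript's share in a fraction changed beyond its change in Input was tested as a shift. Positive shifts outnumbered negative ones in all 5 fractions. They numbered 2592 against 48 in 40S, 1887 against 91 in 80S, 1575 against 260 in disome, 1313 against 57 in Polysome1 and 1125 against 54 in Polysome2. Most positive shifts lay at low abundance, in 5 bins by the mean TPM of the libraries compared. In 40S the lowest 3 bins, up to 1.62 TPM, held 180, 806 and 804 of them. In Polysome2 they held 224, 393 and 308, up to 2.50 TPM. On the log2(TPM + 1) scale, a transcript near 0 in a fraction of both genotypes gets a positive shift when it falls in Input. In the highest bin disome had 61 positive and 126 negative, while positive ones were still more in 40S (224 and 28), 80S (87 and 36), Polysome1 (64 and 19) and Polysome2 (40 and 17). In the highest bin by the mean over all 36 libraries they were more in 40S (81 and 38) and Polysome1 (25 and 20), and fewer in 80S (26 and 36), disome (14 and 141) and Polysome2 (17 and 18). With a filter of 10 TPM disome had 70 positive and 60 negative, and with culture as a replicate block 2707 and 1310. The median log2 shift of those that rose was 1.75 in Polysome2 and 1.89 in 40S, against medians over all transcripts of 0.27 and 0.55. ENST00000600794.1 had a negative shift in Polysome2 of -6.12 (SE 1.04, limma adjusted p = 0.0003922), and ENST00000464611.1 one of -6.53 (SE 1.60, limma adjusted p = 0.01932). ENST00000542931.6 and ENST00000417652.5 had positive shifts in Polysome2 (limma adjusted p = 0.04008 and 6.007e-11), with both listed at 0 in KO Input or below 0.0001 TPM and at 0 in KO Polysome2.

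Most positive shifts belonged to transcripts that were lower in KO Input. Of the 1125 positive shifts in Polysome2, 1084 were also called lower in KO Input, and 38 were called higher in KO Polysome2. The median log2 fold change of the 1125 was -1.82 in Input and -0.05 in Polysome2. In 40S, 2538 of 2592 were called lower in KO Input and 3 higher in KO 40S. A shift contains the Input difference, so the first of these counts is not independent of it.

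The shift counts also moved with single cultures. Without KO replicate 3 they were 9908 in 40S, 5455 in 80S, 5075 in disome, 3743 in Polysome1 and 2572 in Polysome2. Without KO replicate 1 they were 803, 764, 683, 570 and 523 in the same order, and without KO replicate 2 they were 693, 636, 719, 460 and 432. Without WT replicate 3 they were 1643 in 40S, 1242 in 80S and 1148 in disome. With KO replicates 1 and 2 left out together they were 146, 175, 209, 166 and 190. After ERCC scaling the majority turned negative in Polysome1, with 352 negative and 135 positive, and in Polysome2, with 3762 negative and 198 positive. The negative share was 1.82% in 40S and 4.60% in 80S, and after quantile normalization 23.4% and 18.9%, with 23.9% in 40S after median-of-ratios scaling. The main fit leaves aside that Input and fraction libraries come from the same cultures. With culture as a replicate block the shifts numbered 7518 in 40S, 4246 in 80S, 4017 in disome, 2618 in Polysome1 and 2041 in Polysome2.

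The composition of the fractions was described in WT cells against WT Input. In WT 40S, 353 transcripts were higher and 21694 lower than in Input, in WT 80S 1578 were higher and 9879 lower, and in WT Polysome2 1672 were higher and 4499 lower. The median log2 fold changes of those higher and lower were 2.27 and -1.88 in 40S, 2.09 and -1.64 in 80S, and 2.18 and -1.43 in Polysome2, against -0.95, -0.33 and -0.15 over all transcripts. ENST00000600794.1 was higher by 8.77 in WT Polysome2 than in WT Input (SE 0.74, limma adjusted p = 5.882e-10), at 565, 868 and 353 TPM. ENST00000464611.1 was higher as well, at 4197, 6312 and 2265 TPM (limma adjusted p = 7.829e-06). Both were present in every WT gradient fraction, at means of at least 261 and 1010 TPM. Their differences from WT Input are therefore not particular to Polysome2. Why the unfractionated sample listed so little of them was not tested. ENST00000417652.5 fell to a listed 0 in all 3 WT Polysome2 libraries (limma adjusted p = 6.882e-15), and ENST00000542931.6 fell to 0, 0 and 41.2 TPM (limma adjusted p = 0.0004478). These 4 were chosen for their difference from the same 3 WT Input libraries in the KO Input comparison, so their values in the 2 comparisons are not independent.

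The direction in WT Polysome2 changed with abundance, in 5 bins by the mean TPM over the 6 libraries compared. In the highest bin 672 transcripts were higher and 303 lower than in Input, and in the lowest bin 13 were higher and 124 lower. With a filter of 10 TPM the majority over all tested transcripts turned, to 907 higher and 327 lower. It turned too after scaling to the ERCC total, to 32209 higher and 626 lower in Polysome2 and 3055 higher and 993 lower in 80S, where the median log2 fold changes became 2.57 and 0.43. The share of lower calls was 98.4% in 40S, 86.2% in 80S and 72.9% in Polysome2. After quantile normalization it was 59.7%, 64.9% and 61.8%, and after median-of-ratios scaling it was 66.1% in 40S and 67.5% in 80S. Without WT replicate 3 the counts were 12392 in 40S, 4327 in 80S and 4103 in Polysome2. Without WT replicates 1 and 2 they were 7497 and 6029 in 80S and 3207 and 2764 in Polysome2, and 9622 in Polysome2 without KO replicate 3.

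**Figure D4:**
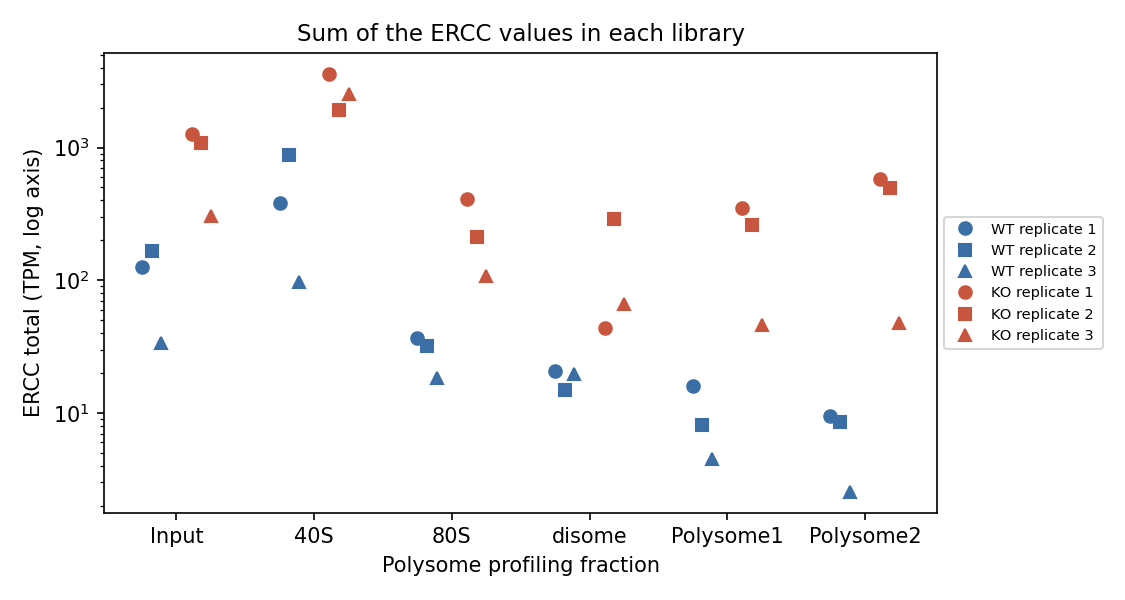
Sum of the ERCC spike-in values in TPM (vertical log axis) in each library, by fraction (horizontal axis), with WT in blue, KO in red and a symbol per replicate. In each of the 6 fractions the 3 KO libraries lie above the 3 WT libraries; in Polysome2 they span 47.8 to 579 TPM against 2.55 to 9.41 TPM.

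The ERCC spike-in rows were higher in KO than in WT in every fraction. The KO and WT means were 888 ± 513 and 109 ± 68.3 TPM in Input (SD, n = 3), 2683 ± 842 and 451 ± 394 in 40S, and 375 ± 286 and 6.82 ± 3.73 in Polysome2. No KO library overlapped a WT library of the same fraction. The exact permutation p was 0.1 in each fraction (two-sided, adjusted 0.225), the smallest that 3 against 3 can give. Averaged over the 6 fractions, the geometric mean was 11.3 times higher in KO cultures (exact permutation p = 0.1, n = 3 per genotype). It was 505, 505 and 152 TPM in KO cultures 1, 2 and 3, and 42.1, 41.0 and 15.5 TPM in WT cultures 1, 2 and 3.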

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

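The tests weighed here on the excess of lower calls in Input, on the shifts and on the ERCC rows, and the expected outcomes of the sample splits, were written after the results were seen. The shifts themselves were planned.

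The KO against WT difference in each gradient fraction differed from that in Input for many transcripts by the interaction test: 2640 in 40S, 1978 in 80S, 1835 in disome, 1370 in Polysome1 and 1179 in Polysome2. A change of the Input libraries alone requires few shifted transcripts to be called in the fraction itself. Of the positive shifts, 0.116% of 2592 in 40S, 0.212% of 1887 in 80S and 0.508% of 1575 in disome were called higher in the KO fraction. The shares were 2.06% of 1313 in Polysome1 and 3.38% of 1125 in Polysome2. Only 7, 32 and 21 transcripts were called higher at all in 40S, 80S and disome, so the low shares there decide little. In Polysome1 and Polysome2, 809 and 970 of the 51052 tested were called higher. Unrelated lists would give low shares there as well, so these decide little too. A change of Input alone remains open for the positive shifts. Of the negative shifts, 6.25% of 48 in 40S, 29.7% of 91 in 80S, 26.5% of 260 in disome, 43.9% of 57 in Polysome1 and 57.4% of 54 in Polysome2 were called lower in the KO fraction. A shift contains the fraction's own difference, so these shares do not decide whether Input alone accounts for the negative ones. A change of ribosome association after loss of RBPMS also remains open for shifted transcripts present in the fraction, and was not tested apart from it; ENST00000417652.5, listed at 0 in all 6 Polysome2 libraries, is not among them.

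The excess of lower over higher calls in KO Input bears on every shift. An exchange of Input and fraction libraries within KO cultures 1 and 2 would need a fraction library there that holds the transcripts found in WT Input and absent from WT fractions, and the highest share found in one was 4.17%, which argues against it. Material like that of the gradient fractions in KO Input replicates 1 and 2 remains a candidate explanation, since 100% of the 13 transcripts present in WT fractions and absent from WT Input were present in both, against 46.2% in KO Input replicate 3. Rare transcripts missed in the KO libraries may add to the excess. The share of lower calls was 74.6% in the most abundant of 5 bins by mean TPM in the Input libraries and 93.9% in the least abundant. It was 63.0% with a filter of 10 TPM, and 45.2% in the most abundant bin over all 36 libraries, a binning tied to the direction. These shares do not decide it. TPM values sum to a fixed total, and the 100 most abundant transcripts took 55.2% of KO Input and 39.8% of WT Input libraries on average. All other transcripts together therefore had a smaller share in KO Input, which lowers their values. After quantile normalization the median log2 fold change was 0.00, and 68.9% of calls were still lower. How much of the excess comes from the fixed total was not tested. An effect of RBPMS loss on RNA levels remains open and was not tested apart from these.

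ERCC rows, which no comparison used, were higher in every KO library than in every WT library of the same fraction. The KO means were 888 TPM in Input, 2683 in 40S, 243.5 in 80S, 133 in disome, 219.6 in Polysome1 and 375 in Polysome2, and the WT means 109, 451, 28.9, 18.5, 9.55 and 6.82. A few deviating ERCC rows are argued against, since 100% of the 54 ERCC rows seen in Input libraries had a higher mean in KO. Less endogenous RNA per amount of spike-in could give the difference, but in 7 of 12 groups the library with the highest ERCC total held fewer transcripts than the one with the lowest, which does not decide it. A spike-in amount that differed with genotype cannot be told apart from it, because the amounts added are not given in the sources used here.

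Other splits of the 6 cultures into 3 and 3 number 10 with the real one, too few for a share under 0.05. In Input 1 of 10 splits gave as many calls as the real 10192, and the highest other gave 891. In Polysome1 it was 1 of 10, with 2769 real and 198 as the highest other. In 40S, 80S, disome and Polysome2 it was 2 of 10: the real counts were 12, 306, 1420 and 2817, and the highest others 498, 375, 5495 and 2904. The exceeding split was in each case KO replicates 1 and 2 with WT replicate 3 against the rest, and in 40S and disome it called several times the real count, which points to a structure of the samples other than genotype. For the shifts it was 1 of 10 in each, with highest others of 30 in 40S, 37 in 80S, 32 in disome, 26 in Polysome1 and 49 in Polysome2. For WT 40S, 80S and Polysome2 against WT Input it was 1 of 10 splits of the 6 libraries, with real counts of 22047, 11457 and 6171 and highest others of 4, 36 and 337. These splits exchange libraries across cultures and leave aside that Input and fraction libraries come from the same 3 cultures.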

How the results depend on the processing

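Tests chosen after the data were seen were the filter of 10 TPM, culture as a random block, the 3 scalings and leaving out KO replicates 1 and 2 together. A count is said to have moved where it differed by more than 1.5 times from the reported one, and counts of the 14 comparisons not listed stayed within 1.5 times. Except where a setting tests fewer transcripts or fewer samples, the cause was not tested. Sequencing depth is unknown, so what depth limits was not tested.

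With a pseudocount of 0.1, KO against WT counts moved to 6579 in Input, 138 in 40S, 72 in 80S, 174 in disome, 591 in Polysome1 and 1161 in Polysome2. Shifts moved to 970 in 40S, 666 in 80S, 810 in disome, 446 in Polysome1 and 401 in Polysome2, and WT fractions to 7063 in 80S and 3330 in Polysome2. With no filter, over 175737 transcripts, KO against WT counts moved to 21500 in Input, 20 in 40S, 469 in 80S, 1704 in Polysome1 and 1688 in Polysome2. Shifts moved to 5602 in 40S, 4436 in 80S, 4042 in disome, 3550 in Polysome1 and 3443 in Polysome2. WT fractions moved to 38285 in 40S, 23333 in 80S and 17409 in Polysome2. With at least 10 TPM in at least 3 libraries, over 14905 transcripts, KO against WT counts moved to 1631 in Input, 87 in 40S, 12 in 80S, 512 in disome, 518 in Polysome1 and 837 in Polysome2. Shifts moved to 103 in 40S, 77 in 80S, 130 in disome, 63 in Polysome1 and 53 in Polysome2. WT fractions moved to 6478 in 40S, 2597 in 80S and 1234 in Polysome2. With only the libraries compared in the fit, KO against WT counts moved to 40 in Input, 0 in 40S, 0 in 80S, 0 in disome, 0 in Polysome1 and 0 in Polysome2. Shifts moved to 764 in 80S, 286 in disome, 303 in Polysome1 and 240 in Polysome2, and WT fractions to 9408 in Polysome2. For the 5 counts of 0 in that limma fit, between 3322 and 11750 transcripts had an unadjusted p under 0.05.

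After quantile normalization, KO against WT counts moved to 6731 in Input, 1142 in 40S, 740 in 80S, 262 in disome, 882 in Polysome1 and 1364 in Polysome2. Shifts moved to 731 in Polysome2, and WT fractions to 13424 in 40S. After median-of-ratios scaling, KO against WT counts moved to 2370 in 40S, 1200 in 80S, 80 in disome, 578 in Polysome1 and 1447 in Polysome2. After scaling to the ERCC total, KO against WT counts moved to 0 in 40S, 12241 in 80S, 27302 in disome, 39131 in Polysome1 and 39009 in Polysome2. Shifts moved to 98 in 40S, 101 in 80S, 119 in disome, 487 in Polysome1 and 3960 in Polysome2, and WT fractions to 4048 in 80S and 32835 in Polysome2. In 40S that limma fit left 682 transcripts at an unadjusted p under 0.05. With KO replicates 1 and 2 left out together, KO against WT counts moved to 656 in Input, 28 in 40S, 34 in 80S, 89 in disome, 96 in Polysome1 and 195 in Polysome2. Shifts moved to 146 in 40S, 175 in 80S, 209 in disome, 166 in Polysome1 and 190 in Polysome2. With culture as a random block, KO against WT counts moved to 691 in 80S, 3124 in disome, 5804 in Polysome1 and 5939 in Polysome2. Shifts moved to 6688 in 40S, 4182 in 80S, 3911 in disome, 2739 in Polysome1 and 2262 in Polysome2, and WT fractions to 17651 in 80S and 10641 in Polysome2.

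With the replicate number or the culture as a replicate block, KO against WT counts moved to 24 in 40S, 1045 in 80S, 3117 in disome, 5670 in Polysome1 and 5300 in Polysome2. Shifts moved to 7518 in 40S, 4246 in 80S, 4017 in disome, 2618 in Polysome1 and 2041 in Polysome2, and WT fractions to 18424 in 80S and 11140 in Polysome2. Samples share only a number here: WT and KO libraries of one number and fraction deviated from their group means with r of -0.709 to 0.107 in 18 pairs, 1 of them above 0.1. Libraries of one culture did so with a median r of 0.338 (-0.146 to 0.833) in 90 pairs, 68 of them above 0.1. Within KO cultures these r ran from 0.294 to 0.833, and within WT cultures from -0.146 to 0.502. As a hint from the data, 32 of 36 libraries correlated best with their own culture among the cultures of their genotype.

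Leaving out each culture in turn gave 3302 to 22990 in Input, 2 to 1241 in 40S, 12 to 11700 in 80S, 28 to 15382 in disome, 27 to 18612 in Polysome1 and 273 to 17515 in Polysome2 for KO against WT. It gave shifts of 693 to 9908 in 40S, 636 to 5455 in 80S, 683 to 5075 in disome, 460 to 3743 in Polysome1 and 432 to 2572 in Polysome2, and for WT fractions 12392 to 26283 in 40S, 4327 to 16491 in 80S and 2764 to 9622 in Polysome2. The highest of these counts came without KO replicate 3 in all 14 comparisons. Leaving out KO replicates 1 and 2 together leaves 1 KO library per fraction, whose own spread is unknown. The majority direction turned under none of the settings for the Input comparison, for the shifts of 40S, 80S and disome, or for WT 40S. The higher share of the 10 most abundant transcripts in KO 40S reversed to 0.977 times the WT mean for 100 transcripts. The planned count tests and normalizations, the stricter count filter, scaling without mitochondrial and ribosomal protein genes and the gene list tests were not run, because the table held TPM without gene names.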

Other observations

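The tests in this part were all chosen after the data were seen. The gradient fraction in which a transcript had its highest TPM, called its peak, could be compared without the Input libraries. Each TPM value is a share of the RNA of its own fraction. The peak is therefore not the place in the gradient where most copies of the transcript lie. Among 7537 transcripts with a mean of at least 10 TPM, the WT mean was highest in Polysome2 for 3351 (44.5%), in Polysome1 for 1614, in disome for 1542, in 80S for 569 and in 40S for 461. In KO the numbers were 3100 in Polysome2 (41.1%), 2535 in Polysome1, 406 in disome, 1086 in 80S and 410 in 40S. The shares differed between KO cultures: Polysome2 held the peak of 33.2%, 21.3% and 48.2% of transcripts in KO cultures 1, 2 and 3, and of 40.8%, 41.6% and 48.9% in WT cultures 1, 2 and 3. Disome held it for 4.48%, 20.5% and 14.1% in KO cultures and 20.4%, 23.1% and 15.4% in WT cultures, in the same order, so the low number for the KO mean was seen only in KO culture 1, whose disome library had 70.5% of its TPM in 10 transcripts.

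The fraction holding a transcript's peak was the same in 56.4% to 67.8% of transcripts between WT cultures, where the cultures' own shares alone would give a median of 28.8%. KO culture 3 shared the peak with the WT cultures for 55.0% to 58.0% of transcripts, where the shares alone would give 29.2% to 31.2%. KO cultures 1 and 2 did so for 26.1% to 29.0%, where the shares alone would give 21.7% to 25.9%. The 3 KO cultures shared it with each other for 28.7% to 32.8%, where the shares alone would give 22.7% to 27.1%. The difference between Polysome2 and 80S on the log2 scale, across the 51052 tested transcripts, which are not independent replicates, correlated at 0.604 to 0.732 between WT cultures. It correlated at 0.384 to 0.573 between KO culture 3 and the WT cultures, at 0.0936 to 0.229 between KO cultures 1 and 2 and the WT cultures, and at 0.230 to 0.321 between KO cultures.

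In WT, 4406 transcripts were higher and 2267 lower in Polysome2 than in 80S (limma, adjusted p under 0.05). After median-of-ratios scaling the majority turned, with 1985 higher and 3662 lower. The count of 6673 fell to 465, 770 and 1536 without WT replicates 1, 2 and 3. Without KO replicates 2 and 3 it was 4091 and 14259. It was 2811 with a pseudocount of 0.1, 2784 with a filter of 10 TPM and 16407 with culture as a replicate block. Of the 10 splits of the 6 libraries, which leave aside that both fractions come from the same cultures, 1 gave as many calls, and the highest other gave 8.

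A hypothesis that loss of RBPMS moves transcripts between monosomes and heavy polysomes was tested as the KO against WT difference in Polysome2 relative to 80S, which leaves Input out. Of 51052 transcripts, 16 were higher and 30 lower (limma, adjusted p under 0.05), with 4551 at an unadjusted p under 0.05. Of the 10 splits of the cultures 1 gave as many as these 46 calls, and the highest other gave 14, with too few splits for a share under 0.05. The count was 2, 0 and 1471 without KO replicates 1, 2 and 3, and 19 without WT replicate 1. It was 4 with a pseudocount of 0.1, 30 after median-of-ratios scaling, 0 with a filter of 10 TPM (1245 at an unadjusted p under 0.05) and 1117 with culture as a replicate block, of which 520 were higher and 597 lower. Polysome2 and 80S come from the same cultures, so the count depends on whether culture is blocked, and such a movement remains open. In the peaks and correlations above, KO culture 3 was nearer to the WT cultures than KO cultures 1 and 2 were. What separates the KO cultures, and which of them shows the effect of RBPMS loss, was not tested.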
